A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

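RNA was measured in 6 libraries of budding yeast of the W303 background, 3 of wild type and 3 of a strain labelled mms21RINGD, an allele of MMS21 (the gene of a SUMO ligase, an enzyme that attaches the small protein SUMO to other proteins). Per the labels' protocols, cells were grown to exponential phase in rich medium with added amino acids, total RNA was extracted with acidic phenol-chloroform, ribosomal RNA was depleted, and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the authors' tools were CASAVA 1.8.2, TopHat2 2.0.8 and edgeR 3.8.6, with the genome build sacCer3 and no role given for any of them. The read counter, the annotation and the strand setting are not given in the sources used here, so reads of a gene and of an antisense partner cannot be separated.

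The authors deposited 1 table of RPKM values, reads scaled to gene length and to library size, with 7126 features and 1 column for each of the 6 libraries. Columns were assigned to samples by their titles, and groups and replicate numbers were taken from the titles as well. The labels do not say whether replicates came from separate cultures started from separate colonies, so p-values measure the spread between these libraries. Names, positions and gene lengths came from the RefSeq annotation of the R64 assembly, the same assembly as sacCer3. Of the 7126 features, 6048 matched by systematic name and 114 by symbol. The 964 unmatched features included 276 tRNA genes and 679 open reading frames with systematic names.

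Sequencing depth was read back from the RPKM values. The product of value and gene length was a whole multiple of 1 step per library, within a tolerance of 0.02 of a read, for 99.8% of the values above 0 in each library, and 6148 matched features were whole in all 6 libraries. Of 283 matched features with introns, 281 were whole with the full gene span as length, so the authors' RPKM was per kilobase of gene span. The library totals were 24.6, 20.9 and 21.7 M reads for wild type replicates 1, 2 and 3 and 19.3, 24.0 and 20.1 M reads for mms21RINGD replicates 1, 2 and 3. A floor of 3 reads in a gene of 1 kb corresponded to 0.122 to 0.156 RPKM. Intervals on read numbers are exact 95% Poisson intervals and cover counting error only. Replicates were compared with a chi-square statistic over 5662 features. Its median was 2.11 times the value for counting noise between wild type replicates 2 and 3, and 1.64 to 2.26 times between pairs of mutant libraries, so no library was a copy of another. It was 16.4 and 21.6 times for wild type replicate 1 against replicates 2 and 3.

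Because the values are RPKM and not counts, they were tested on a log scale. Features with a mean of at least 1 RPKM over the 6 libraries were fitted as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, a moderated linear model with a variance trend and no covariate. The test was two-sided with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was a call. Every log2 fold change below is mutant minus wild type on the log2(RPKM + 1) scale, which understates the change of genes with low values, and each adjusted p of a gene is from this limma fit. A number after ± is the standard error beside the log2 fold change of a gene, and the SD of 3 libraries elsewhere. A fold is the ratio of mean RPKM. With 3 libraries against 3, an exact two-sided permutation test of a single value cannot go below p = 0.1.

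Gene lists were tested with camera (limma), which compares a list with the other genes, with a preset correlation of 0.01 between genes and adjustment over 42 lists (1 of them is not reported here), and again with the correlation estimated from the data. The fry test asked whether a list moved 1 way on balance. Chromosomes were compared by their median log2 fold change minus that of all features, with 0.3 and non-overlapping groups as the condition for a call. Genes within 25 kb of a chromosome end were tested as a list. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took MMS21, the 12 largest rises and the 12 largest falls among called genes with a standard name, a mean of at least 10 RPKM and groups that did not overlap, and up to 4 members of each list with the smallest p. Every member of the mating type, marker, sporulation, Smc5/6 and SUMO lists could be named too. Genes named outside the rule are said to have been chosen after their values were seen.

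Alternatives were pseudocounts of 0.1 and 5 RPKM, no filter, a filter at 10 RPKM, median-of-ratios scaling, quantile normalization, rescaling to the total without structural and mitochondrial RNAs, limma without a trend or with robust estimates, the replicate number as a block, and leaving out each library. Added after the data were seen were voom weights on the recovered reads, restriction to matched features, a correction for gene length and GC content, and leaving out the right end of chromosome XII. The fit was tested on simulated data for this comparison, drawn for 5915 matched features. It called 94 of 100 features changed 2-fold, 80 of 100 changed 1.5-fold and 8 of 5715 left unchanged. The changed features had a mean of at least 5 RPKM and rose and fell equally often, with independent noise. The data had more calls, most of them higher, so these rates need not hold for them. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes of ribosomal proteins, histones, elongation factors, hexose transporters, tRNAs and subtelomeric families have near-identical copies whose reads the authors' counting could have split. Single members are therefore uncertain, as are the 312 matched features that overlap another gene.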

Results

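The series compared the transcriptome of the mms21RINGD mutant with that of wild type in 3 libraries each, under a title that ties the SUMO ligase Mms21 to the making of ribosomes. Libraries held 19.3 to 24.6 M reads. SCR1, the RNA of the signal recognition particle, took 5.17% to 5.48% of the reads in wild type and 6.51% to 6.70% in the mutant. The first principal component held 76.6% of the variance and separated the groups, with wild type replicate 1 at -16.4, the other wild type libraries at -33.0 and -34.1, and the mutant libraries at 26.4 to 29.8.

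MMS21 itself was higher in the mutant. The gene (YEL019C, chromosome V, 120498 to 121301, minus strand, R64) measured 2.82 ± 0.562 RPKM in wild type (SD, n = 3) and 14.3 ± 1.99 RPKM in mms21RINGD (SD, n = 3), a 5.09-fold difference with a log2 fold change of 2.01 ± 0.15 (limma adjusted p = 0.000152), or 1.303 with a pseudocount of 5 RPKM. The 3 wild type libraries held 64, 51 and 38 reads of the gene, with 95% exact Poisson intervals from 26.9 to 81.7 over the libraries, and the mutant libraries held 257, 249 and 218 reads, with intervals from 190.02 to 290.4. The groups did not overlap, and the exact permutation test gave its smallest possible two-sided p of 0.1. PXP1 (118617 to 120299), the next gene downstream on the same strand, rose 1.94-fold (log2 fold change 0.87 ± 0.11, limma adjusted p = 0.0012). EAF5 (121471 to 122310), the divergent neighbour, measured 13.8 ± 1.63 and 13.1 ± 0.980 RPKM (SD, n = 3 each; limma adjusted p = 0.581), but was called lower with median-of-ratios scaling (log2 fold change -0.24) and with quantile normalization (-0.48). Both neighbours were chosen after their values were seen. A level per gene does not show which part of MMS21 was read, so it does not check the labels.

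**Figure D1:**
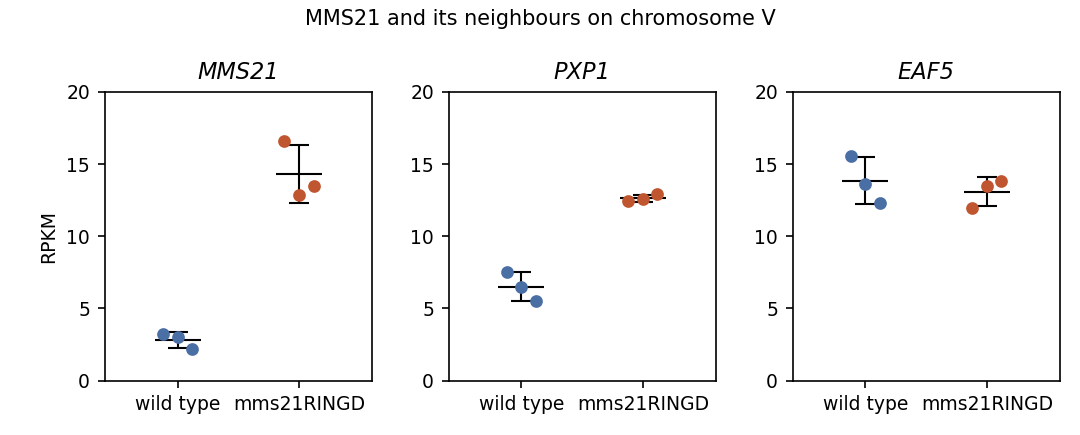
RPKM of MMS21 and of its neighbours PXP1 and EAF5 in each library, with 1 point per library, the mean as a line and the SD as a bar (n = 3 per group). MMS21 lies between 2.18 and 3.23 RPKM in wild type and between 12.9 and 16.6 RPKM in mms21RINGD, while EAF5 overlaps between the groups.

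Across the genome 2875 features were higher and 732 lower in mms21RINGD out of 6731 tested (limma, adjusted p under 0.05), of which 564 rose and 9 fell at least 2-fold. The 2-fold counts moved with the processing: 406 and 20 with median-of-ratios scaling, 289 and 42 with quantile normalization, 675 and 6 with totals without structural RNAs, 314 and 5 with a pseudocount of 5 RPKM, 372 and 5 at 10 RPKM, 715 and 20 without wild type replicate 1 and 490 and 15 without wild type replicate 3. Without wild type replicate 1, 3864 were higher and 1028 lower, and without mms21RINGD replicate 3, 1860 and 433. Lower features numbered 468 without wild type replicate 2 and 459 without mms21RINGD replicate 2. Of the 12 largest rises 7 belonged to the general stress list. DDR2, a gene of the multistress response, rose 89.1-fold (log2 fold change 6.45 ± 0.43, adjusted p = 9.95e-05). HSP12, a small membrane-associated heat shock protein gene, went from 25.3 ± 8.48 to 2199 ± 186 RPKM (SD, n = 3 each), and HSP26, a small chaperone gene, from 6.56 ± 1.90 to 426 ± 41.7 RPKM. SIP18 and GRE1, which encode hydrophilins, rose with log2 fold changes of 6.32 ± 0.13 and 5.75 ± 0.13, and PIR3, a cell wall protein gene, with 5.46 ± 0.09. SPG4, EGO4, CPP3, ALD3, MSC1 and RTN2 completed the 12, with log2 fold changes from 4.79 for SPG4 to 4.36 for RTN2.

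The falls were smaller. OLE1, the fatty acid desaturase gene, went from 1744 ± 521 to 687 ± 36.9 RPKM (SD, n = 3 each; log2 fold change -1.29 ± 0.22, limma adjusted p = 0.00419), and IZH4, of a membrane protein family, from 36.7 ± 14.2 to 12.3 ± 0.857 RPKM (-1.42 ± 0.29, adjusted p = 0.00841). PLB2 (phospholipase B), FAA4 (fatty acyl-CoA synthetase), AAH1 (adenine deaminase), RSN1, DBP2 (an RNA helicase), IZH2, the phosphate genes PHM6 and PHO12 and the histone genes HTA2 and HTB2 were the others, with log2 fold changes from -1.16 for PLB2 to -0.77 for IZH2. Wild type replicate 1 lay below the other wild type libraries, toward the mutant, in each of these genes except HTB2. For OLE1 it measured 1143 RPKM against 2052 and 2037, with 650 to 724 in the mutant. For PHM6 it measured 46.0 RPKM against 96.1 and 107, with 33.7 to 38.6 in the mutant. The calls of DBP2, IZH2, PHM6 and PHO12 were lost when any single library other than wild type replicate 1 was left out, with log2 fold changes that stayed between -1.12 (PHM6) and -0.62 (IZH2). That of RSN1 was lost without mms21RINGD replicate 3 and that of PHO12 also with totals without structural RNAs (-0.83). The balance of higher and lower calls moved with the scaling. The median log2 fold change of all features was 0.24 as deposited, 0.33 with totals without structural RNAs, 0.06 with median-of-ratios scaling and -0.10 with quantile normalization, and 79.7%, 88.9%, 58.2% and 37.0% of the calls were higher.

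Genes of the ribosome fell almost as a block. Of 138 measured cytosolic ribosomal protein features, 129 fell, 1 rose and 8 were not called, with a median log2 fold change of -0.52, or -0.76 relative to all features, and -0.31 with quantile normalization. RPS22A went from 4592 ± 136 to 2834 ± 91.7 RPKM, RPS13 from 2408 ± 24.4 to 1563 ± 41.7, RPL8B from 2335 ± 41.5 to 1552 ± 16.9 and RPS2 from 5566 ± 157 to 3696 ± 74.0 (SD, n = 3 each; limma adjusted p = 5.43e-05 for each). Adjusted over the list alone, 131 fell and 1 rose. The exception as deposited was RPS22B, at 730 ± 16.7 and 858 ± 20.3 RPKM (chosen after its values were seen), whose call was lost with median-of-ratios scaling (log2 fold change 0.05). With that scaling 134 members fell and 0 rose, and with quantile normalization 121 fell and 7 rose. RPP1, taken into the list by its name, encodes a subunit of RNase P and not a ribosomal protein, and measured 27.9 ± 1.28 and 26.01 ± 2.19 RPKM (limma adjusted p = 0.321), though it was called lower with median-of-ratios scaling and quantile normalization. The camera test gave an adjusted p of 9.3e-69 with the preset correlation, and adjusted p = 0.203 with an estimated correlation.

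Ribosome biogenesis factors, the proteins that process ribosomal RNA and assemble the subunits, fell less uniformly. Of 144 members 62 fell and 2 rose, with a median log2 fold change of -0.31 (camera adjusted p = 5.61e-27, and adjusted p = 0.625 with an estimated correlation), and adjusted over the list alone 33 fell and 1 rose. NOP10, a core protein of the H/ACA snoRNPs, went from 827 ± 121 to 546 ± 25.01 RPKM and RRB1, a chaperone of ribosomal protein L3, from 168 ± 19.9 to 116 ± 2.74 (SD, n = 3 each). UTP15 and RRP9, of the small subunit processome, fell with log2 fold changes of -0.37 ± 0.07 and -0.32 ± 0.06. The risers, FPR4 (0.41 ± 0.08) and JJJ1 (0.30 ± 0.10), were chosen after their values were seen, and neither was called with median-of-ratios scaling or quantile normalization, where JJJ1 turned to -0.059. The call of JJJ1 was also lost with the replicate number as a block and without wild type replicate 2 or any single mutant library. Wild type replicate 1 stood apart in this list, with a median of -0.26 against 0.14 and 0.12 in the other wild type libraries and -0.32 to -0.31 in the mutant. Without that library 131 members fell and 3 rose, and 102 and 119 fell and none rose with median-of-ratios scaling (median -0.50) and quantile normalization (-0.52).

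Among 19 genes of RNA polymerase I and its factors 8 fell and none rose, with a median log2 fold change of -0.08 that depended on the processing (camera adjusted p = 0.000146, and adjusted p = 0.203 with an estimated correlation). Adjusted over the list alone 4 fell. Wild type replicate 1 lay at -0.11, against 0.09 and 0.00166 in the other wild type libraries, and without it 9 fell and 3 rose. With median-of-ratios scaling 12 fell (median -0.26) and with quantile normalization 15 (-0.41), while the median was 0.01 with totals without structural RNAs, -0.19 after length and GC correction and -0.13 to -0.044 when 1 library was left out. HMO1, a high mobility group protein of the ribosomal DNA, fell from 154 ± 2.61 to 106 ± 1.59 RPKM, RPC40 from 241 ± 36.7 to 168 ± 2.76, and the core subunit genes RPA190 and RPA135 fell with log2 fold changes of -0.46 ± 0.11 and -0.53 ± 0.13. Both of these calls were lost without wild type replicate 2 or 3 or mms21RINGD replicate 3, and that of RPA135 also without mms21RINGD replicate 2. Translation factors fell in 25 of 37 cases and rose in 2 (median log2 fold change -0.26, camera adjusted p = 4.14e-13, adjusted p = 0.203 with an estimated correlation); adjusted over the list alone 25 fell and 3 rose, and the median was -0.45 with median-of-ratios scaling and -0.17 with totals without structural RNAs. TEF4, EFB1 and TEF1, of elongation factor 1, and HYP2, of eIF5A, fell by 0.48, 0.36, 0.36 and 0.34 on the log2 scale, EFB1 not being called with quantile normalization. TIF4632 (0.54 ± 0.09) and HCR1 (0.36 ± 0.06) rose and were chosen after their values were seen. Of 18 aminoacyl-tRNA synthetase genes, 13 fell and none rose (camera adjusted p = 2.64e-09, adjusted p = 0.203 with an estimated correlation), MES1 by 0.51 and GRS1 by 0.36 on the log2 scale; adjusted over the list alone 14 fell.

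The 76 snoRNAs, guides of ribosomal RNA modification, went both ways, with 14 higher and 22 lower and a median log2 fold change of -0.03 whose sign was not stable (camera adjusted p = 2.02e-05, lower than other features; adjusted p = 0.661 with an estimated correlation). Adjusted over the list alone 14 rose and 21 fell. The median was 0.07 both with totals without structural RNAs and after length and GC correction, and -0.068 to 0.013 when 1 library was left out, positive without wild type replicate 2 or 3. With median-of-ratios scaling 3 rose and 23 fell (median -0.21), and with quantile normalization 26 rose and 21 fell, the list was not called and its direction against other genes turned. Wild type replicate 1 lay at -0.13, against 0.03 and 0.07 in the other wild type libraries. snR24, snR39, snR54 and snR77 fell by 0.62, 0.49, 0.69 and 0.59 on the log2 scale; snR24, snR39 and snR54 overlap ASC1, RPL7A and IMD4 in the annotation.

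**Figure D2:**
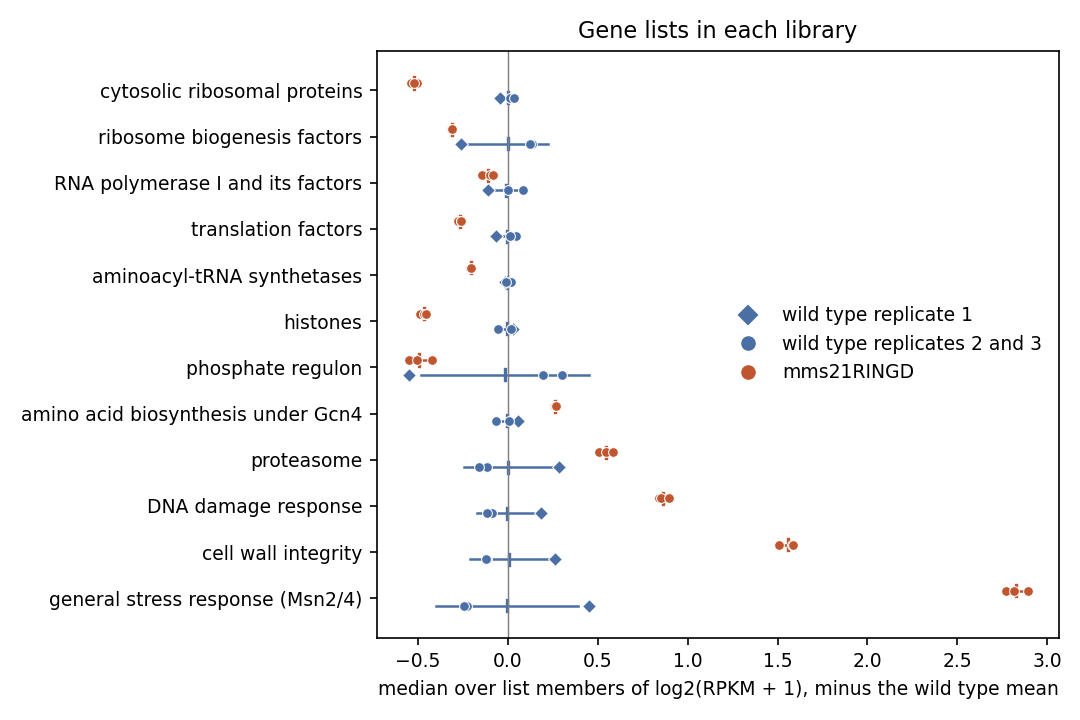
Median over the members of 12 gene lists of log2(RPKM + 1), minus the wild type mean, in each library; points are libraries, short vertical lines group means and horizontal bars the SD (n = 3 per group), with wild type replicate 1 as diamonds. The cytosolic ribosomal protein list lies between -0.54 and -0.51 in the mutant libraries, and the general stress list between 2.77 and 2.89, while the median fold change of the RNA polymerase I list turned positive with totals without structural RNAs.

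Genes under the stress activators Msn2 and Msn4 rose together. All 42 members rose, as they did adjusted over the list alone, with a median log2 fold change of 2.82 (camera adjusted p = 4.14e-13, adjusted p = 0.616 with an estimated correlation). FMP16 rose 17.4-fold beside HSP12, HSP26 and SIP18. In wild type replicate 1 the median of the stress list lay at 0.45 against -0.23 and -0.24 in the other wild type libraries. Cell wall integrity genes rose in 13 of 14 cases (median 1.56, camera adjusted p = 9.87e-05, adjusted p = 0.625 with an estimated correlation), the same number as adjusted over the list alone, and PIR1, chosen after its values were seen, was not called (-0.03). Beside PIR3, SED1 went from 233 ± 48.6 to 1122 ± 70.4 RPKM and GSC2, a glucan synthase gene, from 16.4 ± 0.674 to 72.2 ± 0.819 (SD, n = 3 each), and PRM5 rose 3.67-fold. All 33 proteasome genes rose, also adjusted over the list alone, with a median of 0.57 (camera adjusted p = 0.000703, adjusted p = 0.878 with an estimated correlation), among them RPN4, the activator of proteasome genes (0.62 ± 0.06), and RPN13 (0.70 ± 0.09). Wild type replicate 1 lay above the other wild type libraries in these lists too, at 0.26 for cell wall integrity and 0.28 for the proteasome, against -0.16 to -0.11. Of 22 chaperone genes under Hsf1, 15 rose, 17 adjusted over the list alone, SSA4 by 9.98-fold and SSA3 by 7.80-fold, but the list test did not pass (camera adjusted p = 0.0502). It passed without wild type replicate 1 (0.000611), which lay at 0.42 there, and with median-of-ratios scaling (0.0148) and quantile normalization (1.93e-06).

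Of 20 DNA damage response genes 17 rose and none fell, 17 adjusted over the list alone (median 0.86, or 0.39 with quantile normalization, camera adjusted p = 0.000197, adjusted p = 0.661 with an estimated correlation). HUG1, a checkpoint target, went from 5.95 ± 1.78 to 70.5 ± 5.59 RPKM and RNR3, a damage-induced subunit of ribonucleotide reductase, from 2.18 ± 0.242 to 17.95 ± 0.730 (SD, n = 3 each). RNR2 and RNR4 of the same enzyme rose 1.84-fold and 1.92-fold (limma adjusted p = 3.4e-05 and 5.43e-05). RNR1, TOS4 and RAD53, chosen after their values were seen, did not pass (log2 fold changes -0.07, 0.37 and 0.42), though TOS4 and RAD53 did without wild type replicate 1 or with totals without structural RNAs, and RNR1 was called lower with median-of-ratios scaling. That library lay at 0.19 in this list, against -0.08 and -0.11 in the other wild type libraries. Histone genes went the other way, with 9 of 10 lower, also adjusted over the list alone (median -0.46, camera adjusted p = 3.69e-09, adjusted p = 0.0844 with an estimated correlation). HTA2 fell from 723 ± 41.4 to 389 ± 9.08 RPKM and HTB2 from 658 ± 36.4 to 367 ± 12.01, HTA1 fell by 0.56 and HHF1 by 0.40 on the log2 scale, and HHO1, the linker histone gene, was not called (0.23 ± 0.16, chosen after its values were seen) but was higher without wild type replicate 1 (0.42).

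In amino acid biosynthesis under Gcn4, 31 of 48 genes rose and 3 fell, 33 and 3 adjusted over the list alone, but the list test did not pass (median 0.26, camera adjusted p = 0.128). With median-of-ratios scaling 16 rose and 10 fell (median 0.08), and with quantile normalization 24 and 8, where the list passed (camera adjusted p = 3.08e-05). ARG1 and ARG3 of arginine synthesis rose 6.07-fold and 7.08-fold, HIS4 3.04-fold and SNZ1, of vitamin B6 synthesis, 4.25-fold. The transcript of GCN4 measured 840 ± 42.3 and 837 ± 15.8 RPKM (SD, n = 3 each, limma adjusted p = 0.949). It was called higher with quantile normalization (log2 fold change 0.22, limma adjusted p = 0.0073). ARO2, THR1 and ILV3 fell with log2 fold changes of -0.30, -0.28 and -0.41; these genes and GCN4 were chosen after their values were seen.

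Genes of the Smc5/6 complex and of the SUMO pathway did not pass the list test (camera adjusted p = 0.562 and 0.415). Of 8 Smc5/6 genes 5 rose, the same number as adjusted over the list alone: MMS21, SMC6 (1.58-fold), KRE29, NSE1 and SMC5. With median-of-ratios scaling 3 rose and 1 fell, and with quantile normalization 2 and 4. The calls of KRE29 and SMC5 were lost with median-of-ratios scaling (0.17 and 0.065). Those of KRE29, NSE1 and SMC5 did not hold with quantile normalization, where SMC5 was lower (-0.24). The call of SMC5 was also lost with the replicate number as a block and without any single library other than wild type replicate 1. Of 13 SUMO genes 7 rose, also 7 adjusted over the list alone, among them CST9 (1.87-fold), SLX8 (1.71-fold) and ULP1 (1.40-fold, not called with quantile normalization). With median-of-ratios scaling 3 SUMO genes rose and 1 fell, and with quantile normalization 2 and 5. With quantile normalization both medians turned negative, at -0.14 and -0.11. The list medians were 0.29 and 0.25 as deposited, close to the 0.24 of all features. SMC6 and CST9 lie between the ribosomal DNA and the right end of chromosome XII, a part whose genes were mostly higher (below).

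No chromosome passed the condition for a call, and chromosome XII had the highest median, 0.14 above that of all features in the fit, with 0.140, 0.146 and 0.144 in the mutant libraries. Genes within 25 kb of a chromosome end were higher, with 129 of 217 features up and 12 down and a median log2 fold change of 0.49 (camera p = 0.000314, and p = 0.339 with an estimated correlation). Over all features 2875 of 6731 were up and 732 down, with a median of 0.24. The genes near chromosome ends were not compared with genes of matched expression level. Among the features with a mean of at least 10 RPKM this list did not pass (median 0.29), and over all its features the median was 0.29 with a pseudocount of 5 RPKM, 0.32 with median-of-ratios scaling and 0.042 with quantile normalization.

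Within chromosome XII the genes were not shifted evenly. The 284 genes between the ribosomal DNA and the right end (489573 to 1067501), a part chosen after its values were seen, had a median of 0.254 ± 0.00435 in the mutant libraries relative to the rest of the nuclear genome (SD, n = 3) and -7.44e-05 ± 0.0121 in wild type (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Of these genes 217 rose and 13 fell.

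**Figure D3:**
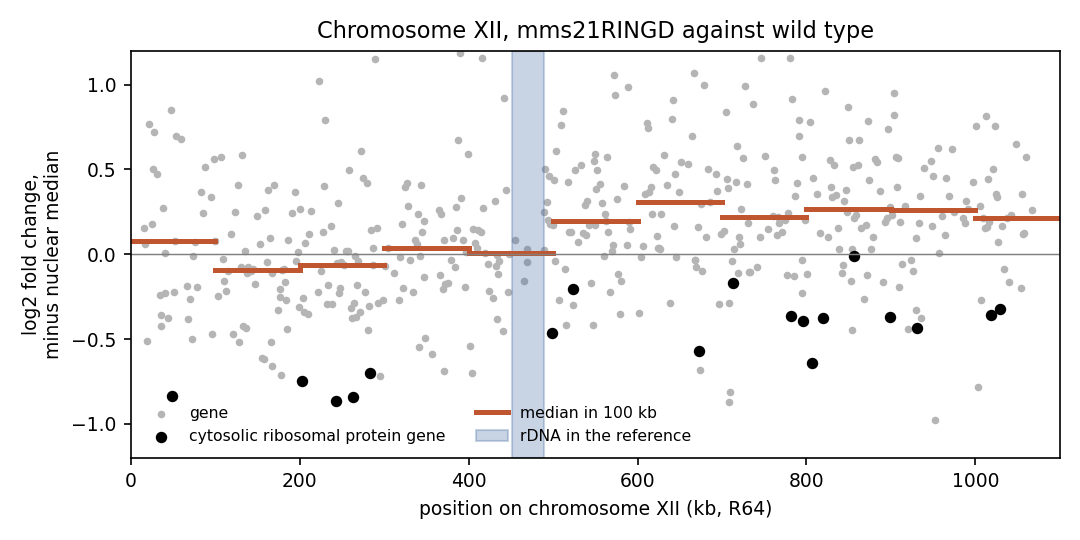
Log2 fold change of each gene of chromosome XII, minus the median of nuclear genes, against position in kb (R64), with cytosolic ribosomal protein genes in black, medians of 100 kb bins as lines and the ribosomal DNA of the reference shaded; 30 of 506 genes lie beyond the axis limit of 1.2. The bins beyond the ribosomal DNA lie between 0.19 and 0.31.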

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

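Among the 309 features below the filter of 1 RPKM, which no comparison above used, 45 were higher and 1 lower in mms21RINGD when the limma fit was run without the filter, an alternative fixed in advance. LDS1, a gene of the spore membrane, measured 0.332, 0.0979 and 0.377 RPKM in wild type and 1.54, 1.49 and 1.42 RPKM in the mutant (limma adjusted p = 0.00184). MAM1, of the meiotic monopolin complex, measured 0.491, 0.527 and 0.355 against 1.71, 1.42 and 1.48 RPKM (adjusted p = 0.00237), and both genes were chosen after their values were seen. They do not stand for the 45: THI12, chosen likewise, had the lowest limma adjusted p (0.00136). The sporulation list itself did not pass (camera adjusted p = 0.277). The value of 0.0979 RPKM lies below the 0.122 to 0.156 RPKM of 3 reads in a 1 kb gene.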

How the results depend on the processing

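Voom, the restriction to matched features, the length and GC correction and the fit without the right end of chromosome XII were chosen after the data were seen. The causes of the changes below were not tested. A fit that left out 1 library also had fewer libraries to estimate the spread from, so a lost call need not depend on that library. MMS21 kept its direction and its call in every alternative that retained it; the filter at 10 RPKM did not. The number of higher features was 1860 to 3864 and of lower features 433 to 1028 when 1 library was left out, the lowest without mms21RINGD replicate 3 and the highest without wild type replicate 1; lower features numbered 468 without wild type replicate 2 and 459 without mms21RINGD replicate 2. Lower features numbered 1441 with median-of-ratios scaling and 474 with totals without structural RNAs, and quantile normalization gave 1369 higher and 2330 lower. Voom called 2745 and 668. With the replicate number as a block 2250 and 549 features were called. Deviations of same-numbered libraries correlated at -0.14, 0.05 and -0.10 and 2 of 6 libraries correlated best with their own number, so the numbers were not taken as pairing. Of 42 lists 19 passed, against 0 with an estimated correlation and 29 with fry, which compares a list with no other genes. The estimated correlation ended the calls of cytosolic ribosomal proteins (median -0.52), ribosome biogenesis factors (-0.31), RNA polymerase I (-0.079), snoRNAs (-0.025), translation factors (-0.26) and subtelomeric genes (0.49). Fry did not call ribosome biogenesis factors (-0.31), snoRNAs (-0.025), the phosphate regulon (-0.49), mitochondrial ribosomal proteins (0.40) or tRNAs (0.12), which camera called. The Gcn4 list passed with fry (0.26), at 10 RPKM (0.26) and with quantile normalization (0.16), and subtelomeric genes did not pass at 10 RPKM (0.29). Direction against other genes turned with quantile normalization for snoRNAs (-0.013, not called), glycolysis (0.11) and ergosterol synthesis (0.085), and after length and GC correction for tRNAs (0.31, not called). That fit held matched features alone, without the 276 unmatched tRNA genes, so the few tRNAs left are not the list fitted elsewhere; restriction to matched features alone also ended the call (0.19). Fry, which has no such reference, gave a positive direction for tRNAs (0.12), purine and pyrimidine synthesis (0.090), glycolysis (0.020) and G2/M genes (0.16), and also, called by neither test, for RNA polymerase III, mitochondrially encoded, haploid-specific and ergosterol genes. Quantile normalization reversed GCN4 (0.22), KRE29 (-0.045), SMC5 (-0.24), MFA2 (0.068), JJJ1 (-0.059), RPL41B (0.15), RPL15B (-0.22), RPS1A (0.16) and RPL6B (0.17). The shift of distal chromosome XII was 0.20 to 0.27 over the settings. Over the named genes and all alternatives, 2329 values kept direction and call or stayed uncalled, the latter whatever their sign. Another 71 lost the call, 24 gained it and 9 reversed with a call in either fit. Depth limits the lowest genes, since 3 reads in a 1 kb gene are 0.122 to 0.156 RPKM.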

Other observations

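The tests of distal chromosome XII, of wild type replicate 1 and of explanations for the level of MMS21 were chosen only after the results were seen. So were those of the splits and of snoRNAs inside other genes. The tests of gene lists, of chromosome medians and of the MMS21 level itself were planned. Several groups outside the ribosome moved. All 10 citric acid cycle genes rose, with IDH1 and IDH2 of isocitrate dehydrogenase at 2.99-fold and 2.83-fold (camera adjusted p = 0.0345, and adjusted p = 0.878 with an estimated correlation), all 10 also adjusted over the list alone; the list did not pass with totals without structural RNAs (adjusted p = 0.0720). In wild type replicate 1 this list lay 0.58 above the other wild type libraries on the log2 scale, after the median difference of all features was subtracted. Of 21 genes under nitrogen catabolite repression 16 rose, 20 adjusted over the list alone, PUT1 by 4.28-fold and GAP1 by 1.90-fold (camera adjusted p = 0.000926, adjusted p = 0.615 with an estimated correlation), and of 22 iron regulon genes 17 rose, also 17 adjusted over the list alone, FIT2 by 5.94-fold and HMX1 by 2.91-fold (camera adjusted p = 0.0347, adjusted p = 0.878 with an estimated correlation; not called without wild type replicate 1, adjusted p = 0.148, without mms21RINGD replicate 1, at 10 RPKM, with totals without structural RNAs or after length and GC correction); 13 rose with median-of-ratios scaling and 9 with quantile normalization. Among 20 members of subtelomeric families 16 rose and COS10, chosen after its values were seen, fell, 18 and 1 adjusted over the list alone, with AAD6 at 2.60-fold, PAU23 at 2.80-fold and COS1 at 2.05-fold (camera adjusted p = 0.00712, adjusted p = 0.625 with an estimated correlation; 0.144 with quantile normalization, where 7 rose and 4 fell, and 0.151 at 10 RPKM). Of 67 mitochondrial ribosomal protein genes 41 rose and none fell, 49 adjusted over the list alone (camera adjusted p = 0.0076, adjusted p = 0.909 with an estimated correlation), and 67 rose without wild type replicate 1, which lay at 0.27 against -0.15 in both other wild type libraries, but 23 with median-of-ratios scaling and 12 with quantile normalization. Of 14 phosphate regulon genes 8 fell, 9 adjusted over the list alone, VTC1 and VTC3 by 0.52 and 0.70 on the log2 scale (camera adjusted p = 1.42e-05, adjusted p = 0.629 with an estimated correlation; 0.0623 with quantile normalization), and wild type replicate 1 lay at the mutant level there, at -0.55 against -0.55 to -0.42; without it 12 fell.

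Single members moved within groups that did not pass. HXT5 rose 14.4-fold and HXT1 fell by 0.49 on the log2 scale, TDH1 and ENO1 rose 7.05-fold and 2.03-fold, and ADE17 rose 4.63-fold while IMD2 fell by 0.55. DIT1 of the sporulation list rose 2.74-fold and SPS4 fell by 1.06 on the log2 scale. Of 6 a-cell genes 1 rose, AGA2 by 1.33-fold, and 3 fell, among them MFA2 and STE2 from 1448 and 480 RPKM to 1324 and 406. The calls of MFA2 and STE2 were lost without a variance trend, with the replicate number as a block, with totals without structural RNAs and with quantile normalization (where MFA2 turned to 0.068). Both were also lost without any single library other than wild type replicate 1, that of MFA2 also with voom and that of STE2 after length and GC correction. The alpha-cell genes STE3 and SAG1 rose from 0.836 and 7.85 RPKM to 2.47 and 15.8, STE3 not being called with quantile normalization. Of 229 tRNA genes 10 rose and 9 fell, 2 and 1 adjusted over the list alone, with a median of 0.12 that turned to -0.04 with median-of-ratios scaling and -0.37 with quantile normalization, and 13 and 35 fell; the list was called under neither. The camera test placed the list below other features (adjusted p = 0.000164, adjusted p = 0.0844 with an estimated correlation), so median and test differed in sign, as they did for the purine, glycolysis, ergosterol, haploid-specific, mitochondrially encoded and G2/M lists. The 11 snoRNAs inside or overlapping other genes had a median of -0.28 with 7 lower and 1 higher, and the other 65 a median of 0.02 with 15 lower and 13 higher; reads were not separated from those of the host.

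Genes of chromosome XII on the far side of the ribosomal DNA were shifted up in every mutant library, by 0.252, 0.251 and 0.259 on the log2 scale against -0.0121, -0.000139 and 0.0120 in wild type (284 genes from position 489573 to 1067501; exact permutation p = 0.1, the smallest possible), whereas the 209 genes on the near side differed by -0.01. The highest of 1674 overlapping windows of as many consecutive genes elsewhere reached 0.0566. Chromosomes I, III, VI, VIII and IX held fewer genes than a window and gave none. Their medians relative to all features were 0.10, 0.013, 0.12, -0.0019 and 0.080. Of 13 cytosolic ribosomal protein genes on the segment 7 fell, against 122 of 125 elsewhere, where RPL41B, RPL15B and the RNase P gene RPP1 were not called (chosen after their values were seen); RPL37A, RPS30A, RPL26A, RPS1A and RPL6B on the segment were not called and RPS22B rose. These counts depended on the scaling and on wild type replicate 1, without which RPL26A, RPS1A, RPL6B and RPL41B were called lower. With median-of-ratios scaling RPL26A, RPS1A and RPL6B on the segment and RPL41B and RPP1 elsewhere were called lower and RPS22B was not called. With quantile normalization RPL37A, RPS30A, RPS1A, RPL6B and RPL41B were called higher and RPL15B and RPP1 lower, RPL37A and RPS30A were higher with totals without structural RNAs, and after length and GC correction RPS30A was higher and RPL41B lower. The medians of the genes on the segment and elsewhere were -0.12 and -0.54 (permutation p across genes = 1e-05 for their difference, the smallest possible). Genes are not independent replicates. The segment was chosen after the values of its genes, these included, were seen, so this p is no separate support for the shift. SIR3, EST1 and RIF2, which rose, lie there too, EST1 and RIF2 not being called with quantile normalization.

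A length or GC bias would have vanished with the correction for both, which left 0.26. Expression level was tested with 10000 random lists matched on it, of which 0 were as high. An extra copy of the segment in every haploid cell would give a shift near 1, and the highest library shift was 0.259. Extra copies in part of the cells, as might follow when the right arm fails to separate at the ribosomal DNA, remain a hypothesis: the 6 bins of 100 kb beyond the ribosomal DNA all had a shift over 0.1, but no DNA was measured, so that a change in transcription of the arm cannot be told apart from it.

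On the first principal component and in lists such as ribosome biogenesis factors, wild type replicate 1 lay between the other wild type libraries and the mutant or near the mutant. This did not hold throughout. On the second component it lay at 18.4, against 1.08 and -14.1 in the other wild type libraries and -6.63 to 1.72 in the mutant. Its median went past the mutant for the unfolded protein response (0.31, against 0.14 to 0.23). For histones it lay at 0.03, against -0.48 to -0.46 in the mutant. Mutant RNA in that library would give 1 share of the mutant change in every list, but the share was 85.7% over the summed RPKM of ribosome biogenesis factors and 6.65% over the stress list, and the library's shift on distal chromosome XII was -0.01. The share was first taken as the median over called members (77.7% and 7.61%) and changed to all members after those values were seen. The length and GC correction left the ribosome biogenesis list at -0.53 relative to the other wild type libraries, against -0.54 without it. The median difference of all features was subtracted in both values. A different growth state of that culture may account for the pattern. The difference of replicate 1 from replicate 3 correlated across genes with that of the mutant from replicate 2 (Pearson r = 0.303, Spearman 0.547). The difference of replicate 2 from replicate 3 against that of the mutant from replicate 1 gave Pearson r = -0.139. Genes are not independent replicates. Culture records were not analysed here, so that growth state cannot be told apart from other sources of the difference.

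For MMS21, scaling was argued against by the lowest log2 fold change over the scalings, 1.49, and reads from EAF5 by its value of -0.070. The smaller rise of PXP1 (0.87) does not decide on reads from that gene, since it started from a higher level. PXP1 measured 5.55 to 7.55 RPKM in wild type and 12.5 to 12.9 RPKM in the mutant, where MMS21 measured 12.9 to 16.6. The 366 genes with 2 to 4 RPKM in wild type rose less in the median (0.60, against 2.01 for MMS21), but 5.74% rose more. They were picked by their wild type level alone, and ALD3, GRE1, CPP3 and PIR3, of the 12 largest rises, were among them. That share therefore cannot decide whether a rise shared with weakly expressed genes accounts for part of the change, which remains open. The allele itself may alter the level of its transcript, which was not tested. The number of called features, 3607, was set against the other splits of the 6 libraries: 1 of 10 splits, the real one, gave as many, and the highest other gave 0 (limma, with up to 308 at an unadjusted p under 0.05). With 10 splits a share under 0.05 cannot be reached.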
